A study of Homo sapiens with 78 samples.

How the data were processed

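RNA of MCF-7 cells, an established estrogen receptor-positive breast cancer line, was compared on 2-colour cDNA arrays of 26618 clones. Each array held a treated sample in one dye and its control in the other, and each comparison was repeated on a second array with the dyes exchanged. There were 78 arrays in 39 such dye pairs, which fell into 18 groups. Of these, 16 were siRNA knockdowns against a non-silencing siRNA, 13 of a single gene and 3 of a pair of genes, and the others were 10 nM estradiol and 100 nM tamoxifen, each against ethanol. A dye pair counted as 1 replicate, because the titles describe the second array as a swap of the first. The channel labels of the siRNA and tamoxifen arrays number the RNAs of a pair differently, so it is not certain that both arrays held the same RNA. The CCNG2, STC2 and tamoxifen groups held 3 replicates and the other 15 groups held 2. The estradiol cells were grown in RPMI medium and all other cells in MEM, per the labels. Per the labels, at least 2 different siRNAs were used for a gene, without saying which replicate received which.

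The deposited values are, per array and clone, a signed score that the authors' table gives without a stated unit, log base or normalization method. The score behaves as a log ratio of the dyes: array medians lay between -0.03 and 0.06, and the interquartile range within an array between 0.117 and 0.395. Because the log base is unknown, no fold changes are given, and every size printed is a difference on this log scale. The labels place the treated sample in Cy3 on the forward arrays and in Cy5 on the swapped ones. No value was missing, and no depth is known; the number of arrays limits the precision.

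The rule for the direction, written before the data were examined, would have taken dye pairs whose arrays correlate above 0 as already turned to treated over control, and this rule was not kept. Over all clones the median r within a dye pair was 0.129 (lowest -0.494, highest 0.427), and 29 of 39 pairs were above 0. However, 8287 of 18128 rows, or 45.7%, carried a dye effect past the threshold, and a dye effect raises that correlation. This effect is what both arrays of a pair share as deposited. Were the values already turned, a response common to the groups would appear as the same effect, so it does not decide the direction. Nor do the calls over the 18 groups, 8933 with the swapped arrays turned and 25229 with them not turned. Of the 56 dye pairs of all clones of silenced genes in their own knockdowns, whether or not they passed, 38 gave opposite signs on both arrays, 31 of them with the treated sample lower, and 18 gave the same sign. Given the dye placement in the labels, the values were therefore read as Cy3 over Cy5, and the swapped arrays were multiplied by -1. Of the 14 measured combinations of a silenced gene and its knockdown, 13 then had a mean below 0 and 7 passed the threshold, against 1 with the arrays not turned. The polarity is thus likely rather than stated, and it was taken from all knockdowns together, never per sample. Because the choice used the silenced genes, their fall is not independent evidence of knockdown.

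Clones were named through the gene table supplied with the reference, where 20965 clones carried 1 gene symbol, and 20952 of those symbols were matched by Entrez ID. Clones of a gene were averaged, which gave 12475 genes, and the 5653 clones with several symbols or none were tested singly, so that each comparison tested 18128 rows. Where "genes" are counted without a qualifier, these unnamed rows are included.

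Both arrays of a dye pair were averaged, and the 39 replicates were fitted as 18 group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 21 residual degrees of freedom), so that all groups share an estimate of the spread. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the rows of its comparison. Each group was tested against 0. The shared estimate covers groups with narrow arrays, such as TP53 knockdown (interquartile ranges of 0.125 to 0.155), and wide ones, such as AKT2 knockdown (0.26 to 0.395). It may be too large for the former and too small for the latter, so counts are not directly comparable between groups. Further contrasts were each double knockdown minus each of its single knockdowns, the double minus the sum of its singles, AKT1 minus AKT2 knockdown, and the mean of all 16 siRNA groups. The p-values measure only the spread between these samples, which may be technical since the labels do not call the replicates separate cultures. The spread of the controls on their own is not in the test, as treated and control RNA were measured as a ratio.

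A set of 19 gene lists fixed beforehand was tested in all 18 groups with limma's camera at a preset correlation between genes of 0.01, adjusted over 342 tests. Estimated correlations and limma's fry were run beside it. The 19 lists were also tested in the mean of all siRNA groups, with preset and estimated correlations. These tests were added after the data were seen and were adjusted over the 19 lists alone. Similarity between groups was described by correlations over all rows, with unchanged groups that share a control simulated for comparison. Apart from the additions named as such, the groups, tests, lists and most alternatives were fixed before the data were examined. The rule for named genes was fixed then too. It takes each silenced gene in its own knockdown and wherever it passed, and the 8 genes with the largest means each way for ESR1, FOXA1, XBP1 and TP53 knockdown, estradiol and tamoxifen. For every other comparison it takes 3 each way. All of these have the same sign in every replicate and are past the threshold; where nothing passed, the 3 of lowest p were taken. It also takes up to 4 passing members of each called list, or 2 of lowest p where none passed.

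The alternatives centred each array on its median, kept each array as a sample with the dye pair as a random block, added a replicate block, and fitted the siRNA or drug groups alone. Others tested each clone separately, left out each replicate in turn, read each knockdown against the mean of the other knockdowns, and left out 1 ESR1 array whose channel carries a second label that its title lacks. A dye term, arrays left unturned, removal of the mean dye profile, and the mean of the groups that do not silence a gene were added after the data were seen. No row had a missing value, so the planned restriction to rows measured on every array moves nothing and was not run. Tested on simulated data over 18128 rows, the fit recovered 80% of genes changed by 0.3 in the ESR1 design of 2 replicates, 96.2% in the CCNG2 design and 94.7% in the tamoxifen design of 3 replicates. All genes changed by 0.6 or 1 were recovered, with 7, 12 and 8 false calls. The simulation gave both arrays of a pair the same noise and every array the same dye effect, which cancels in the pair mean. Group means of the data still correlated with the mean dye profile (for example r = -0.477 in AKT1 knockdown). The simulated rates therefore do not cover a dye effect that does not cancel. Figures were drawn with Python matplotlib 3.10.9. No sample was left out of the main analysis.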

Results

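Transcript levels in MCF-7 breast cancer cells were measured on 78 2-colour cDNA arrays, which compared treated with control RNA on each array. The series concerns genes in the estrogen receptor network of these cells. Single knockdowns targeted AKT1, AKT2, BCL2, CCNG2, ESR1, FOXA1, HSPB8, MAPK1, STAT5B, STC2, TMEM45B, TP53 and XBP1, and double knockdowns targeted ESR1 with CCNG2, ESR1 with MAPK1 and MAPK1 with STAT5B. A further pair of groups received 10 nM estradiol, the natural ligand of the estrogen receptor, or 100 nM tamoxifen, a drug that binds the same receptor. Each value is the mean log ratio of treated over control ± SD over n replicates, where a replicate is a dye-swapped pair of arrays and n = 2 unless stated. The log base is unknown, the direction of the ratio is likely rather than stated, and the number of arrays limits the precision.

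The silenced genes were examined first, though the direction of all arrays was chosen with them, so that their fall is not independent evidence of knockdown. CCNG2, which encodes cyclin G2, fell in its own knockdown (-1.29 ± 0.077, n = 3, adjusted p = 2.1e-10), as did STC2, a secreted glycoprotein hormone (-0.82 ± 0.23, n = 3). XBP1, a transcription factor of the unfolded protein response, fell as well (-1.05 ± 0.082), and so did the kinase gene AKT2 (-0.26 ± 0.0062) and the membrane protein gene TMEM45B (-0.37 ± 0.097). The AKT2 clone, however, gave as deposited -0.729 forward and -0.195 swapped in replicate 1, and -0.467 and 0.0492 in replicate 2. With the arrays not turned its mean was -0.335, so more of its signal ran with the dye than with the treatment. ESR1, which encodes estrogen receptor alpha, fell in the ESR1 knockdown (-0.56 ± 0.084, adjusted p = 8.51e-07), although its pair of clones differed: 1 gave -0.99 ± 0.0011 and the other -0.13 ± 0.17. FOXA1, a pioneer factor that opens chromatin for the receptor, fell in its knockdown (-0.46 ± 0.091), again with 1 clone at -0.93 ± 0.054 and the other at 0.0052 ± 0.13. HSPB8 (-0.12 ± 0.27), STAT5B (-0.09 ± 0.069) and BCL2 (-0.0012 ± 0.026, mean of 6 clones) did not pass in their own knockdowns. No clone carried the symbol AKT1, MAPK1 or TP53, so these knockdowns could not be checked. In the double knockdowns ESR1 as a gene did not pass with CCNG2 (-0.20 ± 0.046) or with MAPK1 (-0.074 ± 0.0085), while the clone that fell most in the single knockdown gave -0.51 ± 0.078, which passed, and -0.23 ± 0.029, which did not. CCNG2 stood at 0.17 ± 0.12 in the ESR1 and CCNG2 double knockdown, and STAT5B at -0.057 ± 0.027 in the MAPK1 and STAT5B one. Groups are named by their labels throughout, although the labels of the 3 doubles and of HSPB8, STAT5B, BCL2, AKT1, MAPK1 and TP53 knockdown are not borne out by a fall of each targeted transcript. With either replicate left out, AKT2 (-0.26 and -0.27), TMEM45B (-0.44 and -0.30) and XBP1 (-0.99 and -1.11) no longer passed in their own knockdowns. Against the mean of the other knockdowns, STC2 (-0.14), XBP1 (-0.56) and TMEM45B (-0.35) did not pass in their own knockdowns either. STC2 fell further with AKT2 (-1.27), ESR1 (-1.34) and FOXA1 knockdown (-1.34), and XBP1 with FOXA1 knockdown (-1.74). A fall of STC2 or XBP1 thus does not by itself single out its own siRNA.

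**Figure D1:**
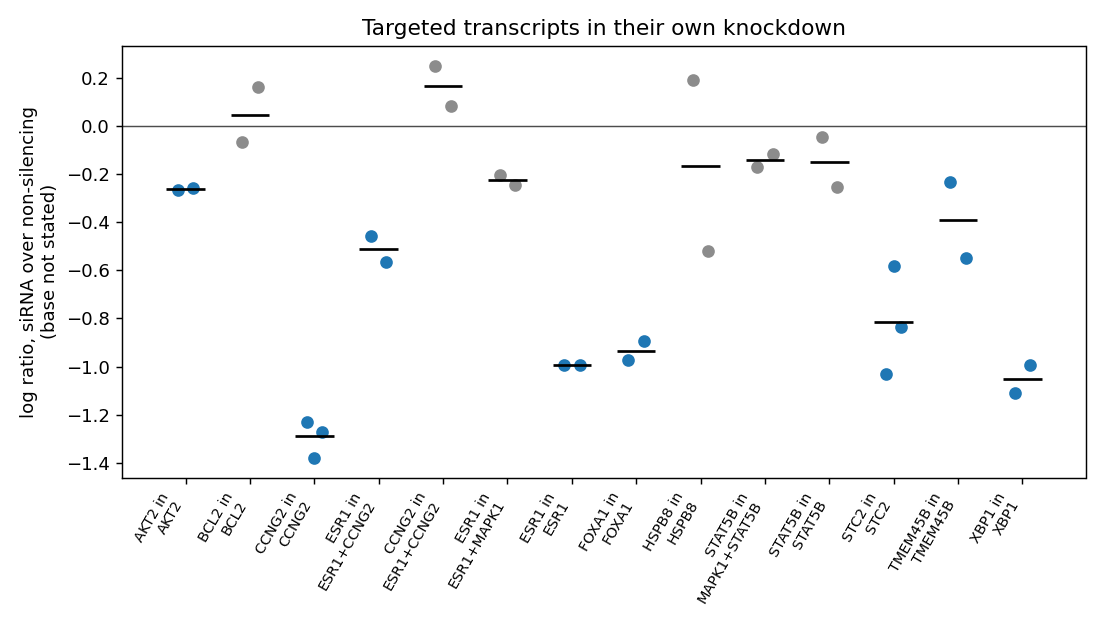
Log ratio of treated over control (log base unknown) of each measured silenced gene in its own knockdown, with 1 clone per gene and group, that of lowest p; points are replicates (blue where the clone passed the test, grey where it did not) and bars the means. The clones of CCNG2, XBP1, ESR1 and FOXA1 lie lowest, with means of -1.29, -1.05, -0.99 and -0.93.

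ESR1 knockdown asks what the receptor maintains in these cells. STC2 (-1.34 ± 0.056), SLC7A5, an importer of large neutral amino acids (-1.14 ± 0.037), and XBP1 (-0.94 ± 0.023) fell most. The histone gene H4C3 (-0.92 ± 0.15) and FEN1, a flap endonuclease of lagging-strand synthesis (-0.71 ± 0.066), also fell, as did the somatostatin receptor SSTR1 (-0.70 ± 0.064) and TMEM64 (-0.76 ± 0.094). FNIP2, a folliculin partner, averaged -0.74 ± 0.75 and rests on 1 replicate, with -0.21 when replicate 1 is left out. The linker histone H1-2 (0.71 ± 0.21), TBC1D9 (0.70 ± 0.42), the desmosome-associated p53 effector PERP (0.68 ± 0.022) and BAK1, which promotes apoptosis by permeabilising mitochondria (0.66 ± 0.12), rose. So did the proline-degrading enzyme gene ALDH4A1 (0.60 ± 0.21), the progranulin gene GRN (0.59 ± 0.31), ECH1 of fatty acid oxidation (0.56 ± 0.26) and MAN1B1, a mannosidase of the secretory pathway (0.52 ± 0.13). TBC1D9 and GRN no longer passed without replicate 2 (0.41 and 0.37).

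Of 37 measured proliferation genes, 20 fell, none rose and 17 did not pass with ESR1 knockdown; adjusted over the list alone, 24 fell. NUSAP1 of the mitotic spindle (-0.61 ± 0.28), RRM2 of deoxynucleotide synthesis (-0.58 ± 0.0078), the securin PTTG1 (-0.54 ± 0.045) and the cyclin-dependent kinase CDK1 (-0.47 ± 0.097) were among them. Of 32 estrogen-induced genes, 17 fell and 15 did not pass (21 fell and 1 rose adjusted over the list alone), including the protease gene PRSS23 (-0.39 ± 0.0056), the chemokine gene CXCL12 (-0.37 ± 0.081) and TPD52L1 (-0.29 ± 0.088). Both lists stood below the other genes also with an estimated correlation (adjusted p = 0.000567 for proliferation, adjusted p = 0.00108 for estrogen-induced genes). In the list of the ATF4 and amino acid response, 3 of 12 fell, namely STC2, SLC7A5 and its heavy chain SLC3A2 (-0.28 ± 0.00051), and in that of STAT5 targets 2 of 9 fell, CCND1 (-0.44 ± 0.18) and PIM2 (-0.30 ± 0.078). The calls of these smaller lists were lost with an estimated correlation (adjusted p = 0.0951 and adjusted p = 0.249). HSPB8, a small heat shock protein gene, fell (-0.30 ± 0.00033). In all, limma called 886 genes, 459 higher and 427 lower (442 and 445 with each array centred on its median). Of 28 named calls 17 passed in every run without a replicate; the count was 176 without replicate 1, and with the mean dye profile removed 333 were higher and 454 lower. Of replicate 2, 1 array carries a second label, and its values had an r of -0.143 with replicate 1, against 0.472 for its dye partner. Without this array the count was 5145, with replicate 2 then in 1 dye orientation only, in which a dye effect does not cancel.

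FOXA1 knockdown shared several of these genes. XBP1 (-1.74 ± 0.044, adjusted p = 3.96e-06) and STC2 (-1.34 ± 0.057) fell most, followed by GDF15, a stress-induced cytokine (-0.79 ± 0.13), FEN1 (-0.58 ± 0.18), histone H4C3 (-0.49 ± 0.14), the calcitonin receptor CALCR (-0.48 ± 0.14) and histone H2AZ1 (-0.44 ± 0.17). ESR1 fell too (-0.28 ± 0.051), whereas CCNG2 rose (0.40 ± 0.05). ASS1, which makes argininosuccinate in arginine synthesis, rose (1.34 ± 0.94), with a value of 0.68 when replicate 2 is left out. PERP (0.96 ± 0.16), the kallikrein protease KLK6 (0.81 ± 0.29), the estrogen-hydroxylating cytochrome CYP1B1 (0.78 ± 0.0076), the sialomucin CD164 (0.74 ± 0.011), TBC1D9 (0.62 ± 0.13), the keratin KRT13 (0.58 ± 0.20) and the antiproliferative BTG1 (0.50 ± 0.083) also rose. Of the 37 proliferation genes 1 fell, RRM2 (-0.23 ± 0.077), and 3 fell adjusted over the list alone; the list's call was lost with an estimated correlation (adjusted p = 0.337). Among 7 reference genes TBP rose (0.22 ± 0.032), with 4 higher adjusted over the list alone, and among 34 cytosolic ribosomal protein genes RPL6 rose (0.29 ± 0.15; 0.18 and not passing without replicate 1). These calls were lost too (adjusted p = 0.165 and adjusted p = 0.469 with an estimated correlation). limma called 374 genes, 143 higher and 231 lower; with each array centred on its median 106 were higher and 329 lower. The count was 30 without replicate 2 and 61 without replicate 1, and 7 of 21 named calls passed in both runs.

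ESR1 and FOXA1 knockdown had 19 genes higher in both, against 3.62 for independent lists, and 22 lower in both, against 5.44. Over all rows their means correlated with r = 0.358 (rho = 0.326), where rows are not independent replicates. Their covariance was 0.00388, and unchanged groups that share a control gave a simulated r of 0.494 and a covariance of 0.00199. The simulation shared controls by replicate number and gave them as much of the spread as the treated RNA. Differences between replicates 1 and 2 had a median r of -0.00694 over pairs of siRNA groups. Sharing of that size was thus not seen, and the simulated values do not measure what shared controls add here. The non-silencing controls are numbered alike across groups and may be the same RNA. Part of the overlap and covariance may thus come from shared controls.

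Estradiol against ethanol asks which genes the receptor's ligand moves. XBP1 rose (0.92 ± 0.17), along with the transcription factors MYC (0.57 ± 0.0067) and FOS (0.57 ± 0.047), the progesterone receptor PGR (0.50 ± 0.0011), the estrogen-responsive EEIG1 (0.65 ± 0.13), the ETS factor ELF1 (0.48 ± 0.011) and PGA5, a pepsinogen (0.80 ± 0.15). The olfactory receptor OR4M2 averaged 0.49 ± 0.45 and gave 0.18 without replicate 2. CCNG2 fell (-0.58 ± 0.033), together with IRF2BPL (-0.65 ± 0.0062), the corepressor TRIM28 (-0.56 ± 0.086), the cytokine-signalling inhibitor SOCS2 (-0.41 ± 0.10), the muscarinic receptor CHRM4 (-0.40 ± 0.12), the ephrin EFNA1 (-0.40 ± 0.05), the KIT ligand KITLG (-0.38 ± 0.081) and the immunoglobulin E receptor FCER2 (-0.37 ± 0.14). Of 32 estrogen-induced genes 7 rose, none fell and 25 did not pass, and 11 rose adjusted over the list alone; CXCL12 (0.38 ± 0.0029) and IGFBP4 (0.42 ± 0.10) were among the 7. This list stood above the other genes also with an estimated correlation (adjusted p = 0.000904). Members known as estrogen targets that did not pass include TFF1 (0.0063) and GREB1 (0.051). The luminal epithelial list had XBP1 as its only riser among 18 genes, and of 12 chaperones none passed, with FKBP4 at 0.27 ± 0.017 and HSPB1 at 0.19 ± 0.0062; 4 chaperones rose adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.152 and adjusted p = 0.21). limma called 78 genes, 53 higher and 25 lower. These cells alone were grown in RPMI medium, and the count was 39 when the drug groups were fitted without the siRNA groups. Of 18 named calls 5 passed in every run without a replicate.

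**Figure D2:**
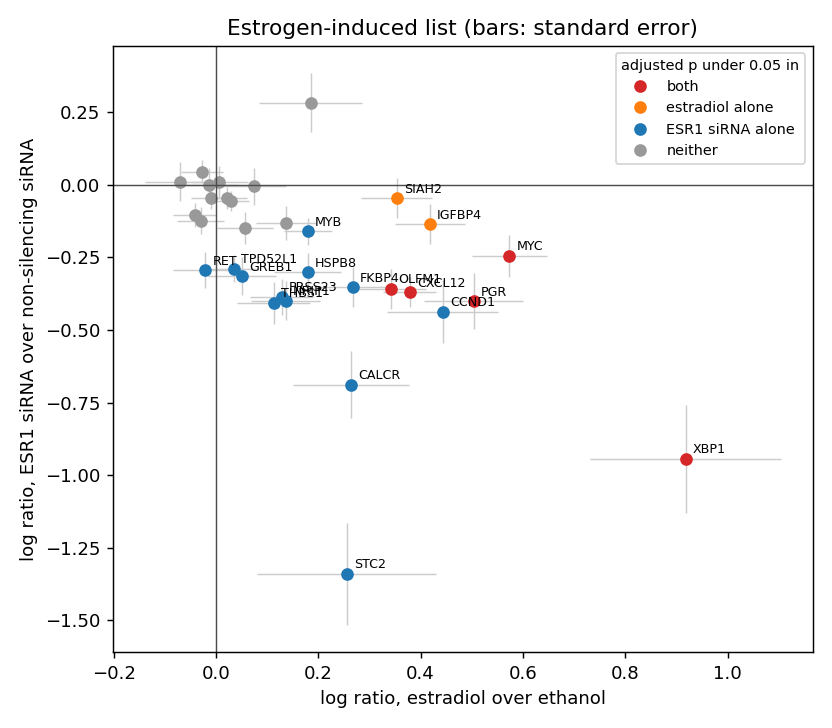
Each point is 1 of the 32 measured estrogen-induced genes of the list fixed beforehand, with its mean log ratio (log base unknown) for estradiol over ethanol on the x axis and for ESR1 siRNA over non-silencing siRNA on the y axis; bars are standard errors, and colour shows in which comparison the gene passed. XBP1 lies at 0.92 and -0.94, STC2 at 0.26 and -1.34, and the list medians are 0.13 and -0.20.

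Genes called in both ESR1 knockdown and estradiol moved mostly in opposite directions. Of these, 11 fell with the knockdown and rose with estradiol, against 1.25 for independent lists, and 4 rose with the knockdown and fell with estradiol, against 0.633; 1 fell in both and none rose in both. The named ones that fell and then rose were XBP1, KLF4, SNX24, PGR, FHL2, CXCL12, OLFM1, MYC, PA2G4 and CRKL, and those that rose and then fell were TGFB3, RNF43 and EFNA1. KLF4, a member of the estrogen-repressed list, stood at -0.46 with the knockdown and 0.46 with estradiol. Over all rows the r of the group means was 0.0395, but the estradiol replicates themselves had an r of -0.0503 over all rows, so this value does not bear on the genes that were not called. These groups do not share a control, because the knockdown was read against a non-silencing siRNA and estradiol against ethanol.

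Tamoxifen against ethanol gave smaller values, with n = 3. The early response gene IER3 (0.63 ± 0.052), MPPED2 (0.43 ± 0.027), FAM234A (0.39 ± 0.026) and CCNG2 (0.39 ± 0.019) rose. So did the elongation factor SUPT4H1 (0.36 ± 0.097), IRF2BPL (0.34 ± 0.064), the zinc transporter SLC39A7 (0.33 ± 0.093) and SCG5, a chaperone of a prohormone convertase (0.33 ± 0.24; 0.21 and not passing without replicate 2). RAMP3, which modifies calcitonin-family receptors (-0.40 ± 0.077), the kallikrein KLK11 (-0.36 ± 0.11), HOPX (-0.36 ± 0.04) and the kinase SGK1 (-0.27 ± 0.011) fell. The channel TRPM6 (-0.24 ± 0.055), YIPF4 (-0.23 ± 0.069), the phosphatase PTPRR (-0.21 ± 0.037) and ZNF776 (-0.19 ± 0.042) fell as well. CCNG2 and IRF2BPL thus fell with estradiol and rose with tamoxifen, and 1 gene did the reverse, but 2 genes were higher with both drugs, and over all rows the r of the drugs was 0.244. Of 22 genes of endoplasmic reticulum stress and XBP1 targets none passed, with PDIA6 at 0.15 ± 0.019 and ATF3 at 0.14 ± 0.049, and 1 rose adjusted over the list alone; the list's call was lost with an estimated correlation (adjusted p = 0.295). limma called 114 genes, 81 higher and 33 lower. The count was 14 when the drug groups were fitted alone, and 28 and 53 without replicate 1 and replicate 2; of 16 named calls 4 passed in every such run.

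XBP1 knockdown moved few genes past the threshold. Besides XBP1, those that fell most were the nucleolar LYAR (-0.52 ± 0.20), THAP10 (-0.40 ± 0.0065), SINHCAF (-0.37 ± 0.17), the pseudouridine synthase TRUB1 (-0.35 ± 0.029), FAM98B (-0.33 ± 0.048), the complement receptor C3AR1 (-0.32 ± 0.027) and VIRMA of the RNA methylation complex (-0.31 ± 0.04). CLMN rose (0.19 ± 0.032). Of 22 genes of endoplasmic reticulum stress and XBP1 targets, 1 fell, the disulfide isomerase PDIA3 (-0.24 ± 0.01), and 8 fell adjusted over the list alone; the list stood below the other genes also with an estimated correlation (adjusted p = 0.0066). None of 37 proliferation genes passed, with TPX2 at -0.17 ± 0.013 and CCNB2 at -0.12 ± 0.041, and the list's call was lost with an estimated correlation (adjusted p = 0.295). limma called 18 genes, 1 higher and 17 lower. CCNG2 knockdown, with n = 3, gave 2348, but limma called only 2 genes in the direct contrast of CCNG2 minus XBP1 knockdown. The lower count thus does not show a narrower response to XBP1 knockdown. None of the 10 named calls passed in both runs without a replicate. The count was 0 without replicate 1 (with 1247 genes at an unadjusted p under 0.05 in the full data), and 0 when the group was read against the mean of the other knockdowns, where XBP1 itself stood at -0.56 and did not pass.

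TP53 knockdown gave 0 genes past the threshold with limma, with 215 at an unadjusted p under 0.05 and 0 with each array kept as a sample. Chance alone would give more than 215 over 18128 rows, and more than in MAPK1+STAT5B (379), BCL2 (647) and STAT5B knockdown (661). The shared spread may thus be too large for these groups, so few calls there do not show that nothing changed. The 3 genes of lowest p did not pass: NCBP2 (-0.32 ± 0.21), TLR9 (0.22 ± 0.014) and PRICKLE2 (0.24 ± 0.092). Of 26 p53 targets none passed and 1 fell adjusted over the list alone. CDKN1A, the p21 cell cycle inhibitor, stood at -0.30 ± 0.22 and ZMAT3 at -0.12 ± 0.056. The list lay below the other genes with the preset correlation (adjusted p = 0.00107), and the call was lost with an estimated correlation (adjusted p = 0.081).

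CCNG2 knockdown (n = 3) lowered, besides CCNG2, the kinase scaffold gene CAB39 (-0.68 ± 0.25), ESR1 (-0.21 ± 0.049), FOXA1 (-0.14 ± 0.058) and STC2 (-0.52 ± 0.12). The autophagy gene WIPI2 (0.63 ± 0.16), the acyl-CoA synthetase gene ACSL5 (0.39 ± 0.14) and the metalloproteinase inhibitor TIMP3 (0.35 ± 0.13) rose. PCCA averaged -0.67 ± 1.07 and rests on replicate 1, with -0.046 without it. Of 22 endoplasmic reticulum stress and XBP1 targets 8 fell, including PDIA6 (-0.32 ± 0.064), PDIA3 (-0.30 ± 0.057) and the signal peptidase subunits SPCS2 (-0.26 ± 0.034) and SPCS3 (-0.24 ± 0.098); adjusted over the list alone 9 fell and 1 rose. Of 37 proliferation genes 9 fell (10 adjusted over the list alone), including MAD2L1 (-0.37 ± 0.24; -0.24 and not passing without replicate 2), AURKB (-0.27 ± 0.17), CENPA (-0.21 ± 0.068) and BUB1 (-0.20 ± 0.094). In the estrogen-repressed list KLF4 (-0.35 ± 0.12) fell besides CCNG2, the silenced gene itself, so that this list's call partly restates the knockdown. These calls were lost with an estimated correlation (adjusted p = 0.0699, adjusted p = 0.295 and adjusted p = 0.273). limma called 2348 genes, 1084 higher and 1264 lower; with each array centred on its median 686 were higher and 1520 lower. The count was 669 without replicate 2 and 1550 without replicate 1, and 9 of 18 named calls passed in every such run.

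STC2 knockdown (n = 3) lowered histone H4C3 (-0.77 ± 0.17) besides STC2, and raised the elongation factor EEF1A1 (0.57 ± 0.08) and the X-linked BEX5 (0.53 ± 0.14) and BEX3 (0.51 ± 0.30). ARHGDIG averaged -0.68 ± 0.98 and rests on replicate 3, with -0.11 without it. CCNG2 averaged 0.31 ± 0.33 and did not pass without replicate 1 (0.12). No fixed list was called in this group. Among 10 markers of non-epithelial cell types the T cell gene CD3D (-0.24) and the endothelial PECAM1 (-0.30) fell. The values hold no intensities, so whether these genes lay above background is unknown and such calls may be technical. limma called 1821 genes, 578 higher and 1243 lower, against 1191 with the mean dye profile removed (323 higher, 868 lower) and 538 without replicate 2. Read against the mean of the other knockdowns, STC2 stood at -0.14 and did not pass, because it lay below 0 in those groups as well.

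AKT2 knockdown lowered STC2 (-1.27 ± 0.11), ESR1 (-0.28 ± 0.082) and AKT2, and raised GANAB, a glucosidase subunit of glycoprotein folding (0.69 ± 0.048), the zymogen granule protein gene GP2 (0.47 ± 0.20) and PERP (0.46 ± 0.11). Several further means depended on 1 replicate: UGDH, which makes UDP-glucuronate (-0.93 ± 0.57), stood at -0.53 without replicate 2, XBP1 (-0.79 ± 0.66) at -0.32 and FOXA1 (-0.20 ± 0.12) at -0.11, both then not passing. Of 22 endoplasmic reticulum stress and XBP1 targets 9 fell (10 adjusted over the list alone), including SSR3 (-0.39 ± 0.14), PDIA6 (-0.38 ± 0.098), DNAJB11 (-0.35 ± 0.052) and SPCS2 (-0.26 ± 0.063). Of 37 proliferation genes 12 fell (13 fell and 1 rose adjusted over the list alone), including PLK1 (-0.28 ± 0.019), PRC1 (-0.28 ± 0.057), MCM2 (-0.26 ± 0.046) and AURKA (-0.26 ± 0.096). Of 34 cytosolic ribosomal protein genes 8 fell and 1 rose (9 and 2 adjusted over the list alone), with RPS7 at -0.41 ± 0.07, RPL14 at -0.35 ± 0.12, RPL7 at -0.36 ± 0.19 and RPS29 at -0.36 ± 0.38; without replicate 2 RPL7 (-0.23) and RPS29 (-0.093) did not pass. These calls were lost with an estimated correlation (adjusted p = 0.0983, adjusted p = 0.277 and adjusted p = 0.59). limma called 2536 genes, 1144 higher and 1392 lower; with each array centred on its median 1288 were higher and 1165 lower. The count was 596 without replicate 2 and 1407 without replicate 1, and 8 of 21 named calls passed in both runs. Among 10 markers of non-epithelial cell types PECAM1 (0.36), CD3D (0.34) and ALB (0.24) rose, while the list was not called (adjusted p = 0.157). Whether these genes lay above background in this epithelial line is unknown, so such calls may be technical.

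AKT1 knockdown gave 0 genes past the threshold with limma, with 1519 at an unadjusted p under 0.05 and 10 with each array kept as a sample. KRABD2 (0.28 ± 0.028), SEPTIN10 (0.23 ± 0.02) and C1QA (0.25 ± 0.031) had the lowest p and did not pass (adjusted p = 0.088 for each). In the direct contrast of these paralogous kinases, AKT1 minus AKT2 knockdown, 817 genes passed, 691 higher and 126 lower. STC2 (0.93), PKDREJ (0.78) and the TGF-beta-induced KLF10 (0.77) were higher after AKT1 knockdown, as were ESR1 (0.30) and AKT2 (0.31), and NOMO2, the prekallikrein gene KLKB1 and the cytochrome oxidase subunit COX7A1 (each -0.45) were lower. None of these 8 calls was kept in every run that left out a replicate, and the count was 18 without AKT1 replicate 2 and 476 without AKT2 replicate 2.

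MAPK1 knockdown lowered STC2 (-0.72 ± 0.26), the co-chaperone DNAJB6 (-0.59 ± 0.11) and the retinoid-induced receptor GPRC5A (-0.55 ± 0.044), and raised the zinc finger genes ZNF267 (0.40 ± 0.14) and ZNF20 (0.34 ± 0.11). Over all rows the replicates of this group had an r of -0.023, so its calls rest on replicates that were not alike as a whole. TTTY6B averaged 0.35 ± 0.46 and gave 0.024 without replicate 1, and the luminal gene ANXA9 averaged -0.38 ± 0.39 and gave -0.098 without replicate 2. Of 12 chaperones none passed and 5 fell adjusted over the list alone, with HSPA8 at -0.33 ± 0.043 and FKBP4 at -0.25 ± 0.046; the list stood below the other genes also with an estimated correlation (adjusted p = 0.0287). Of 32 estrogen-induced genes 5 fell (9 adjusted over the list alone), including KRT13 (-0.41 ± 0.14), IGFBP4 (-0.28 ± 0.049) and CXCL12 (-0.22 ± 0.025), a call lost with an estimated correlation (adjusted p = 0.0983). In the STAT5, proliferation and luminal lists 1 gene each fell, namely SOCS2 (-0.32 ± 0.11), the survivin gene BIRC5 (-0.27 ± 0.044) and ANXA9; these calls were lost as well (adjusted p = 0.22, adjusted p = 0.274 and adjusted p = 0.274 with an estimated correlation). Of 12 genes of the ATF4 and amino acid response only STC2 fell, while 3 genes passed adjusted over the list alone, and this call was lost too (adjusted p = 0.215 with an estimated correlation). limma called 306 genes, 62 higher and 244 lower, against 101 without replicate 1 and 1072 without replicate 2. Of its 12 named calls none was kept in both of those runs.

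TMEM45B knockdown raised the small nucleolar RNA host gene SNHG8 (0.37 ± 0.15) and SPRY3 (0.33 ± 0.14) and lowered GPRC5A (-0.47 ± 0.063) besides TMEM45B. The glycolytic regulator PFKFB4 (0.33 ± 0.23) gave 0.17 without replicate 1 and SLC35F5 (-0.48 ± 0.49) gave -0.13 without replicate 2, both then not passing. Of 12 genes of the ATF4 and amino acid response none passed and 5 rose adjusted over the list alone, with TRIB3 at 0.21 ± 0.15 and the cystine transporter SLC7A11 at 0.19 ± 0.19. None passed in the proliferation (BUB1 -0.22 ± 0.081, CCNB1 -0.18 ± 0.03), endoplasmic reticulum stress (PDIA6 -0.16 ± 0.052, OSTC -0.15 ± 0.042) or chaperone list (HSPA8 -0.20 ± 0.12, DNAJA1 -0.15 ± 0.091). All these calls were lost with an estimated correlation (adjusted p = 0.152, adjusted p = 0.274, adjusted p = 0.215 and adjusted p = 0.27). limma called 67 genes, 45 higher and 22 lower; with each array centred on its median 13 were higher and 15 lower, and with the mean dye profile removed the count was 217. Without replicate 1 it was 15, without replicate 2 206, and against the mean of the other knockdowns 1.

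BCL2 knockdown gave 5 genes, all lower: the luminal keratin KRT8 (-0.55 ± 0.26), NBPF1 (-0.42 ± 0.082), MTERF4 of mitochondrial ribosome assembly (-0.35 ± 0.065) and 2 clones without a gene name. STAT5B knockdown gave 4, all lower, of which KRT8 (-0.52 ± 0.25; -0.34 and not passing without replicate 2) and DCPH1 (-0.48 ± 0.023) are named. Of 32 estrogen-induced genes none passed in BCL2 knockdown (4 fell adjusted over the list alone), with CCND1 at -0.44 ± 0.021 and PRSS23 at -0.24 ± 0.071, and of 37 proliferation genes none passed, with MCM6 at -0.30 ± 0.39 and PCNA at -0.16 ± 0.22. Of 34 ribosomal protein genes none passed, with RPS18 at 0.25 ± 0.19 and RPS12 at 0.21 ± 0.24. These calls of BCL2 knockdown were lost with an estimated correlation (adjusted p = 0.197, adjusted p = 0.165 and adjusted p = 0.274). The luminal epithelial list, with KRT8 as the only member that fell, was called in both groups and lost in both (adjusted p = 0.165 in BCL2 and adjusted p = 0.274 in STAT5B knockdown with an estimated correlation). HSPB8 knockdown gave 0 genes with limma, 1058 at an unadjusted p under 0.05, 3 with each array kept as a sample and 0 with a dye term added; CMAHP (-0.31 ± 0.20), C6 (-0.22 ± 0.046) and GPR173 (-0.24 ± 0.0031) had the lowest p and did not pass. Without 1 replicate the counts ranged from 3 to 16 for BCL2, 0 to 2 for STAT5B and 8 to 14 for HSPB8 knockdown.

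The ESR1 and CCNG2 double knockdown lowered STC2 (-0.81 ± 0.0034), histone H4C3 (-0.78 ± 0.0079), CALCR (-0.77 ± 0.15) and HSPB8 (-0.26 ± 0.067), and raised TBC1D9 (0.53 ± 0.047) and BAK1 (0.42 ± 0.17). Of 37 proliferation genes 14 fell and 23 did not pass (23 fell adjusted over the list alone), including the replication factors GINS2 (-0.56 ± 0.012), MCM3 (-0.35 ± 0.12) and CDC45 (-0.35 ± 0.012) and the cyclin CCNB2 (-0.22 ± 0.03), also with an estimated correlation (adjusted p = 0.00108). Of 32 estrogen-induced genes 6 fell (11 adjusted over the list alone), including PGR (-0.40 ± 0.069) and NRIP1 (-0.29 ± 0.16; -0.17 and not passing without replicate 2), and of 10 estrogen-repressed genes YPEL3 rose (0.45 ± 0.22; 0.29 and not passing without replicate 2). These calls were lost with an estimated correlation (adjusted p = 0.0951 and adjusted p = 0.27). limma called 310 genes, 79 higher and 231 lower, and 131 without replicate 1; 4 of 13 named calls passed in both runs without a replicate.

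The ESR1 and MAPK1 double knockdown lowered SLC7A5 (-0.82 ± 0.03), H4C3 (-0.81 ± 0.13), CALCR (-0.70 ± 0.10) and HSPB8 (-0.31 ± 0.056), and raised KITLG (0.36 ± 0.018), the only named gene that rose. Of 37 proliferation genes 5 fell (15 adjusted over the list alone), including GINS2 (-0.65 ± 0.04), MCM6 (-0.54 ± 0.12), CDC45 (-0.30 ± 0.057) and PCNA (-0.30 ± 0.086), and of 32 estrogen-induced genes 5 fell (8 adjusted over the list alone), including PRSS23 (-0.30 ± 0.02) and CXCL12 (-0.25 ± 0.026). Both lists held with an estimated correlation (adjusted p = 0.000567 and adjusted p = 0.00463). Among 10 estrogen-repressed genes none passed, with CCNG2 at 0.36 ± 0.019 and IL1R1 at 0.27 ± 0.29, and among 12 chaperones HSPB8 fell; these calls were lost (adjusted p = 0.274 and adjusted p = 0.165 with an estimated correlation). limma called 65 genes, 2 higher and 63 lower, but 4 without replicate 1 and 17 without replicate 2, and none of the 11 named calls was kept in both runs.

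The MAPK1 and STAT5B double knockdown gave 1 gene, a clone without a name, which fell. GDAP1 (-0.39 ± 0.21), ISOC1 (-0.48 ± 0.29) and SUPT4H1 (0.39 ± 0.07) had the next lowest p and did not pass. None of 32 estrogen-induced genes passed, with PRSS23 at -0.27 ± 0.16 and CXCL12 at -0.17 ± 0.20, none of 37 proliferation genes, with MCM3 at -0.22 ± 0.013 and RRM2 at -0.14 ± 0.038, and none of 18 luminal genes, with ANXA9 at -0.29 ± 0.28 and TFAP2C at -0.23 ± 0.038. Their calls were lost with an estimated correlation (adjusted p = 0.215, adjusted p = 0.313 and adjusted p = 0.215).

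Direct contrasts asked how far the doubles differ from their singles. Relative to ESR1 knockdown, SSTR1 and FEN1 were higher in both doubles that include ESR1 (0.68 and 0.68 with CCNG2, 0.69 and 0.75 with MAPK1) and ESR1 itself was higher (0.36 and 0.49). The secreted neural protein gene NELL2 was lower in both (-0.60 and -0.55). KLF4 (0.63) was higher and SH3BGRL3 (-0.73) and MPPED2 (-0.59) lower with CCNG2, and TPBG (0.51) was higher and MED26 (-0.51) and the protease inhibitor CSTA (-0.50) lower with MAPK1. These contrasts gave 103 (39 higher, 64 lower) and 39 genes (20 higher, 19 lower). Relative to CCNG2 knockdown, CCNG2 (1.46), CAB39 (0.77) and DYNLT3 (0.75) were higher in the double and SH3BGRL3 (-0.78), LRRIQ1 (-0.76), H4C3 (-0.72) and HSPB8 (-0.36) lower, among 599 genes, 258 higher and 341 lower; with each array centred on its median 357 were higher and 219 lower. ESR1 did not differ past the threshold from CCNG2 knockdown (0.011) or MAPK1 knockdown (0.12). Relative to MAPK1 knockdown, the ESR1 double gave 4 genes, with NOSIP (0.31) named, and the STAT5B double 4, with OGDHL (0.39) and SLC25A25 (0.38) named. Relative to STAT5B knockdown limma called 0, with 268 at an unadjusted p under 0.05 and 0 with each array kept as a sample; SUPT4H1 (0.49), INPPL1 (0.39) and TOX4 (0.34) had the lowest p. Without 1 replicate the contrasts with ESR1 knockdown ranged from 33 to 215 genes for the CCNG2 double and from 4 to 333 for the MAPK1 double, the highest of each without ESR1 replicate 2 and the lowest without ESR1 replicate 1 and double replicate 1. The 599 genes became 155 without double replicate 1, and both contrasts of 4 genes became 232 and 260 without MAPK1 replicate 2, with lowest values of 1 and 0 without replicate 2 of the ESR1 double and replicate 1 of the STAT5B double.

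Non-additivity, the double minus the sum of its singles, passed for 265 genes in the ESR1 and CCNG2 pair, 123 higher and 142 lower (162 and 86 with each array centred on its median). CCNG2 (1.16), DYNLT3 (1.15), FEN1 (0.99) and ESR1 (0.57) lay above the sum, and SH3BGRL3 (-0.93), H1-2 (-0.67) and WIPI2 (-0.62) below it. In the ESR1 and MAPK1 pair 50 genes passed, 31 higher and 19 lower, with STC2 (1.38), NMD3 (0.86), ZWILCH (0.83) and ESR1 (0.68) above the sum and H1-2 (-0.69), TGFB3 (-0.59) and TMPRSS2 (-0.52) below it. Because ESR1 was lowered less in both doubles than in the single knockdown, the sum includes a larger fall of ESR1 than the doubles had. A shift of the shared non-silencing control would also enter the sum 1 more time than the double. Part of the value of STC2, which averaged -0.675 over the groups that do not silence it, could come from this. In the MAPK1 and STAT5B pair 3 clones without a name passed, and OGDHL (0.42), AAGAB (0.63) and GEMIN4 (0.41) had the next lowest p. Without 1 replicate these counts ranged from 96 to 547, from 10 to 248 and from 1 to 237, the highest without ESR1 replicate 2, ESR1 replicate 2 and MAPK1 replicate 2.

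Effects on the transcripts of the other silenced genes address the network of the series' title. Among 166 combinations of a measured target and a group other than its own knockdown, 22 passed, 18 lower and 4 higher, and 37 passed adjusted over the list alone. STC2 was the most frequent, and it fell in the AKT2, CCNG2, ESR1, FOXA1 and MAPK1 single knockdowns and in the ESR1 and CCNG2 double. XBP1 fell in the AKT2, ESR1 and FOXA1 knockdowns and rose with estradiol. ESR1 fell in the AKT2, CCNG2 and FOXA1 knockdowns, FOXA1 in the AKT2 and CCNG2 knockdowns, and HSPB8 in the 3 groups whose ESR1 label is single or double. CCNG2 rose with FOXA1 and STC2 knockdown and tamoxifen and fell with estradiol. The list of study targets was called lower in 10 groups, and in AKT2, CCNG2, ESR1, FOXA1, TMEM45B and XBP1 knockdown it includes the fall of the silenced gene itself; none of these calls held with an estimated correlation (for example adjusted p = 0.0983 in ESR1 and adjusted p = 0.0983 in FOXA1 knockdown). Read against the mean of the other knockdowns, 6 of the 19 calls in siRNA groups were kept: STC2 was lower in AKT2 (-0.62), ESR1 (-0.70) and FOXA1 knockdown (-0.70), XBP1 was lower in FOXA1 knockdown (-1.29), and CCNG2 was higher in FOXA1 (0.40) and STC2 knockdown (0.30). The other 13 did not pass. These were STC2 in CCNG2 (0.17) and MAPK1 knockdown (-0.04) and the ESR1 and CCNG2 double (-0.14), XBP1 in AKT2 (-0.28) and ESR1 knockdown (-0.44), and ESR1 in AKT2 (-0.14), CCNG2 (-0.07) and FOXA1 knockdown (-0.14). They also include FOXA1 in AKT2 (-0.13) and CCNG2 knockdown (-0.079), and HSPB8 in ESR1 knockdown (-0.20) and its doubles with CCNG2 (-0.16) and MAPK1 (-0.20).

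**Figure D3:**
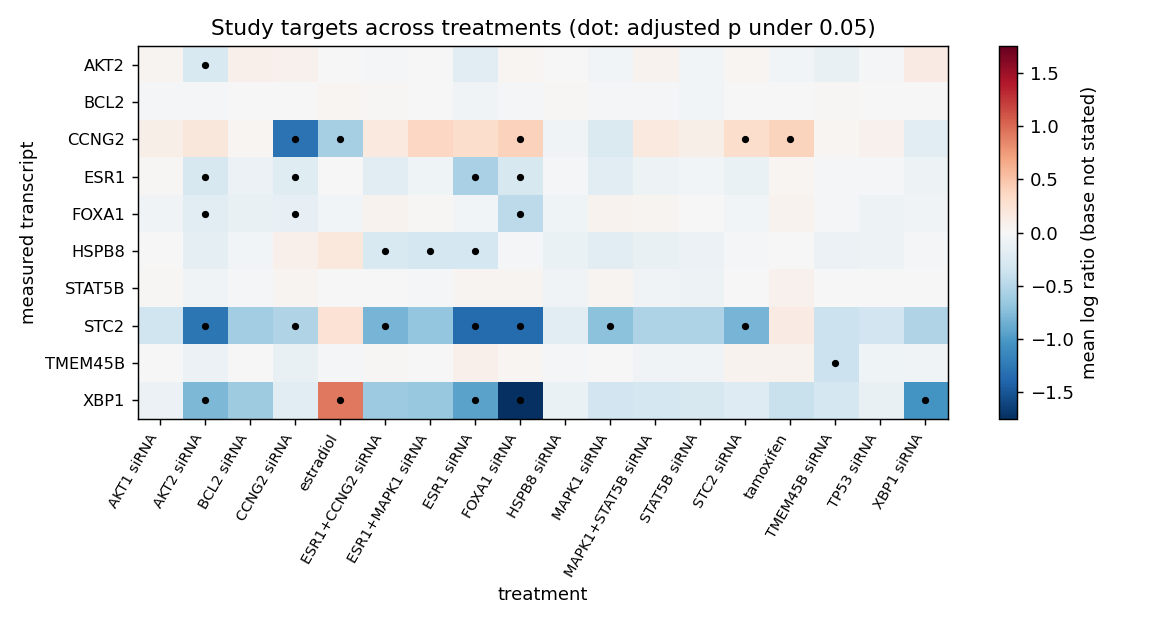
Mean log ratio (colour, log base unknown) of each measured study target in each of the 18 groups; dots mark values past the threshold. STC2 and XBP1 have means below 0 in all 16 siRNA groups.

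The mean of all 16 knockdowns was read against the non-silencing siRNA, with each gene's own knockdowns included. STC2 (-0.68), XBP1 (-0.53) and CALCR (-0.36) fell most, and GANAB (0.46), PERP (0.37) and TBC1D9 (0.21) rose most. ESR1 (-0.14), FOXA1 (-0.07) and HSPB8 (-0.11) also fell. Over the groups that do not silence the gene these means were -0.68 for STC2, -0.49 for XBP1, -0.11 for ESR1, -0.04 for FOXA1 and -0.11 for HSPB8. All passed, though FOXA1 only narrowly (adjusted p = 0.036) and with 5 of 15 groups above 0. Of 37 proliferation genes 24 fell and none rose, and of 32 estrogen-induced genes 14 fell and none rose. Of 22 endoplasmic reticulum stress and XBP1 targets 12 fell and 1 rose, of 18 luminal genes 6 fell and of 12 chaperones 5 fell. These lists held with an estimated correlation (adjusted p = 5.39e-05, 0.00147, 0.00245, 0.0132 and 0.0132). The list tests of this mean were added after the data were seen. They were adjusted over the lists in this mean alone, apart from the tests in the groups. limma called 1666 genes, 560 higher and 1106 lower. A property of the non-silencing control itself would appear in this mean too, since every knockdown was read against it.

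Over the 342 tests of the fixed lists 55 were called, and 8 held with an estimated correlation, all given above. limma's fry, which does not set a list against the other genes, called 44 of the 342. These included endoplasmic reticulum stress and XBP1 targets in AKT2 (fry adjusted p = 1.38e-05) and CCNG2 knockdown (1.6e-05), but not p53 targets in TP53 knockdown (0.0699). Proliferation was called in 11 groups, lower in each, and p53 targets and reference genes in 1 group each. Of the 19 lists, 7 were called in no group: FOXO targets (lowest adjusted p = 0.0629, FOXA1 knockdown), ERK-responsive genes (0.0672, estradiol), interferon response (0.173, BCL2 knockdown), basal and mesenchymal genes (0.397, ESR1 knockdown), markers of non-epithelial cell types (0.157, AKT2 knockdown), cholesterol synthesis (0.156, estradiol) and apoptosis regulators (0.225, HSPB8 knockdown).

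Group profiles over all rows were compared pairwise, with rows not independent replicates. Over the 120 pairs of siRNA groups the median r was 0.121, from -0.403 (FOXA1 with TMEM45B) to 0.651 (CCNG2 with XBP1), where simulated unchanged groups sharing a control gave a median of 0.496. The median covariance was 0.00071 against 0.00199 simulated. The simulated sharing by replicate number was not seen in the data, so the simulated values do not measure what shared controls add. CCNG2 and XBP1 knockdown (rho 0.567, covariance 0.00494 against 0.00131 simulated) had 14 genes lower in both, against 1.19 for independent lists. AKT2 correlated with TMEM45B knockdown (r = 0.612, rho = 0.56, covariance 0.00709 against 0.00204) and FOXA1 with STC2 knockdown (r = 0.478, rho = 0.383, covariance 0.00463 against 0.00134). AKT2 and FOXA1 knockdown were opposed (r = -0.381, rho = -0.413), and 143 genes were higher in AKT2 and lower in FOXA1 knockdown against 14.6 for independent lists. Likewise 589 genes were higher in AKT2 and lower in STC2 knockdown, against 78.4. FOXA1 knockdown and tamoxifen, which share no control, had r = 0.361 (rho 0.341). Both group means also correlated with the mean dye profile (r = 0.189 for FOXA1 knockdown, r = 0.26 for tamoxifen). Part of their likeness may thus run with the dye. The STC2 knockdown mean correlated with that profile more (r = 0.445), so the same limit holds for FOXA1 with STC2 knockdown. For AKT2 knockdown, opposed to STC2 knockdown, this r was -0.0805. Part of an excess of genes moved alike between siRNA groups may come from shared controls. A shared control moves both groups alike, so it would not give the opposed moves.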

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

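The dye term, the arrays left unturned, the removal of the mean dye profile and the mean of the groups that do not silence the gene were chosen only after the results were seen; all other alternatives were planned. Of 306 values of named genes, 241 were called, and their direction and call were kept for 232 with each array centred on its median, 233 with each array as a sample, 231 with a dye term, 233 with the dye profile removed, 214 with siRNA or drug groups fitted alone and 234 with each clone tested separately. All 5 calls of silenced genes in the mean of all knockdowns were kept without their own knockdowns. Against the mean of the other knockdowns 84 of 152 calls were kept. When a replicate was left out, 659 of 945 gene calls were kept and 286 lost, and no called value changed its direction; the lone replicate left in a group of 2 is assumed to vary like the other groups. For genes of a single group named by their largest mean, the kept direction was fixed in advance, since the rule required the same sign in every replicate. The table holds no intensities, so signal over background is unknown. The cause of a moved value was not tested unless stated.

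With each array centred on its median, STAT5B gave 1 gene (4), TMEM45B 28 (67), MAPK1+STAT5B minus MAPK1 0 (4, with 979 at an unadjusted p under 0.05 in the main limma fit) and the non-additivity of MAPK1+STAT5B 1 (3), where the number in parentheses is the count in the main analysis. BCL2 in its own knockdown, at -0.0012, was above 0 when centred (0.0028), with the dye profile removed (0.0031), for its clone of lowest p (0.045) and against the other knockdowns (0.0086).

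With each array kept as a sample, the counts were 10 for AKT1 (0), 27 for BCL2 (5), 111 for ESR1+MAPK1 (65), 3 for HSPB8 (0), 6 for MAPK1+STAT5B (1), 8 for STAT5B (4), 259 for tamoxifen (114) and 206 for TMEM45B (67). They were 88 for ESR1+MAPK1 minus ESR1 (39), 12 for ESR1+MAPK1 minus MAPK1 (4), 2 for MAPK1+STAT5B minus MAPK1 (4), 108 for non-additivity of ESR1+MAPK1 (50) and 10 for that of MAPK1+STAT5B (3). Adding a dye term gave, for the same comparisons, 23 for AKT1, 20 for BCL2, 116 for ESR1+MAPK1, 0 for HSPB8, 6 for MAPK1+STAT5B, 6 for STAT5B, 229 for tamoxifen, 154 for TMEM45B, 68, 10 and 2 for the contrasts, and 94 and 5 for non-additivity. The turned arrays of a pair had a consensus correlation of -0.264, and of -0.185 with the dye term. They were thus no more alike than other arrays of their group. With the mean dye profile removed, AKT1 gave 1, STC2 1191 (1821), TMEM45B 217 and the non-additivity of MAPK1+STAT5B 1.

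With siRNA or drug groups fitted alone, which leaves fewer samples to estimate the spread, STAT5B gave 1, ESR1+MAPK1 minus ESR1 21, MAPK1+STAT5B minus MAPK1 0, the non-additivity of ESR1+MAPK1 21 and of MAPK1+STAT5B 1, estradiol 39 (78) and tamoxifen 14. With each clone tested separately, BCL2 gave 17, estradiol 123, ESR1+MAPK1 110, FOXA1 883 (374), STC2 2844, TMEM45B 249, XBP1 32 (18), ESR1+MAPK1 minus ESR1 77, MAPK1+STAT5B minus MAPK1 2 and the non-additivity of MAPK1+STAT5B 12.

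Against the mean of the other knockdowns, AKT1 gave 18, AKT2 1640 (2536), BCL2 0, ESR1+CCNG2 80 (310), ESR1+MAPK1 8, FOXA1 830, MAPK1 165 (306), MAPK1+STAT5B 2, STAT5B 2, TMEM45B 1 and XBP1 0. There STC2 stood above 0 in BCL2 (0.082), CCNG2 (0.17), MAPK1+STAT5B (0.15) and STAT5B knockdown (0.16), and ESR1 in the ESR1+MAPK1 double (0.073). Without the array that carries a second label, ESR1 knockdown gave 5145 genes (886); replicate 2 then holds 1 dye orientation, so that the 28 named calls kept there do not show stability. With the swapped arrays not turned, 1 of the targeted genes passed in its knockdown (7). With replicates of different number only, which compares single replicates, r was 0.43 for CCNG2 with XBP1, 0.454 for AKT2 with TMEM45B, -0.232 for AKT2 with FOXA1, 0.168 for ESR1 with FOXA1 and 0.268 for FOXA1 with STC2. With an estimated correlation 8 list tests were called (55), and with fry 44.

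The replicate numbers did not pair the samples: over 120 pairs of siRNA groups, the differences between replicates 1 and 2 correlated with a median r of -0.00694, and 21 pairs exceeded 0.1. A replicate block moved the count of BCL2 to 9 and left every other count within 1.5 times (2596 for AKT2, 910 for ESR1, 349 for FOXA1, 1547 for STC2). With this block 48 list tests were called, and 233 of the 241 named calls were kept.

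Leaving out 1 replicate at a time gave counts of 0 to 1 for AKT1, 18 to 476 for AKT1 minus AKT2, 1343 to 1975 for the mean of all knockdowns, 596 to 1407 for AKT2, 3 to 16 for BCL2, 669 to 1550 for CCNG2, 155 to 504 for ESR1+CCNG2 minus CCNG2 and 96 to 547 for the non-additivity of ESR1+CCNG2. Counts ranged over 94 to 105 for estradiol, 131 to 303 for ESR1+CCNG2, 33 to 215 for ESR1+CCNG2 minus ESR1, 4 to 17 for ESR1+MAPK1, 4 to 333 for ESR1+MAPK1 minus ESR1, 1 to 232 for ESR1+MAPK1 minus MAPK1 and 10 to 248 for the non-additivity of ESR1+MAPK1. Further ranges were 176 to 1129 for ESR1, 30 to 61 for FOXA1, 8 to 14 for HSPB8, 101 to 1072 for MAPK1, 0 to 260 for MAPK1+STAT5B minus MAPK1, 1 to 237 for the non-additivity of MAPK1+STAT5B and 0 to 3 for MAPK1+STAT5B. The remaining ranges were 0 to 4 for MAPK1+STAT5B minus STAT5B, 0 to 2 for STAT5B, 538 to 1896 for STC2, 28 to 53 for tamoxifen, 15 to 206 for TMEM45B, 0 to 2 for TP53 and 0 to 11 for XBP1. Among named genes that had not passed, the direction changed between runs for BCL2 (-0.0195 to 0.017) and HSPB8 (-0.31 to 0.066) in their own knockdowns, ESR1 in ESR1+CCNG2 minus CCNG2 (-0.022 and -0.0095 in 2 runs, up to 0.043) and STAT5B in the non-additivity of MAPK1+STAT5B (-0.12 to 0.1, with 0.0082 and 0.038 between).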

Other observations

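The tests of a shared control, of a common control shift and of estradiol-raised genes without ESR1 siRNA for STC2 and XBP1, and of exchanged or mixed siRNAs for CCNG2 and XBP1, were chosen only after the results were seen. The genes of other lists given first were picked after their values were seen. Luminal markers moved in several knockdowns in which their list was not called. AGR2, a disulfide isomerase of secretory epithelium, fell with AKT2 (-0.72) and ESR1 knockdown (-0.45), and the adhesion molecule EPCAM fell with CCNG2 (-0.46) and AKT2 (-0.26) and rose with STC2 knockdown (0.41). With ESR1 knockdown the cadherin CDH1 (0.24) and the epithelial factor ELF3 (0.23) rose, and KRT8, which fell with BCL2 and STAT5B knockdown, rose with FOXA1 knockdown (0.35). CCND1, the cyclin D1 gene, fell with AKT2 (-0.39), CCNG2 (-0.33) and ESR1 knockdown (-0.44) and in the ESR1 and CCNG2 double (-0.43). FOS, which rose with estradiol, fell in that double (-0.37).

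Single members of other lists passed without a call of the list. The glucose-regulated TXNIP rose with ESR1 (0.38) and STC2 knockdown (0.30) and fell with CCNG2 knockdown (-0.25). TRIAP1, an apoptosis inhibitor that p53 induces, fell with CCNG2 (-0.43), XBP1 (-0.28), MAPK1 (-0.23) and AKT2 knockdown (-0.23). With STC2 knockdown the p53 targets DDB2 (0.35), TNFRSF10B (0.28) and CDKN1A (0.24) rose, while GDF15 (-0.37) and the antiapoptotic MCL1 (-0.32) fell. In cholesterol synthesis, SQLE fell with AKT2 (-0.33) and CCNG2 knockdown (-0.30), and HSD17B7 rose with AKT2 (0.35) and fell with STC2 knockdown (-0.35).

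The means of STC2 and XBP1 were below 0 in all 16 siRNA groups, from -1.34 to -0.18 for STC2 and from -1.74 to -0.096 for XBP1. Of 34 siRNA replicates, 33 were below 0 for STC2 and 31 for XBP1. In HSPB8 knockdown the replicates lay far apart (STC2 -0.182 ± 1.11, XBP1 -0.117 ± 0.897). Without the own knockdown, 6 and 3 of 15 groups passed the threshold. Chance values of controls shared by replicate number would make replicate differences correlate between groups, and their median r was -0.00694. A control RNA common to all replicates cancels in these differences, so chance values of such a control stay open. A shift of the non-silencing control as the whole cause would leave no difference between groups, but both genes differed between the 15 groups other than their own knockdown (higher adjusted p of limma's F test 0.0352); such a shift as part of the cause stays open. A lower estrogen response in the knockdowns is a hypothesis that the data leave standing: of 53 genes raised by estradiol, 45 were below 0 in the mean of all knockdowns (23 past the threshold, median -0.04, camera p = 0.000101 with an estimated correlation), partly through the ESR1 siRNA groups, and over the 13 groups without ESR1 siRNA 36 of 52 such genes other than XBP1 were below 0 (12 past the threshold, median -0.02, camera p = 0.00849 with an estimated correlation). Since every knockdown shares the non-silencing control, a response of that control in estrogen targets could give the same values.

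CCNG2 and XBP1 knockdown had profiles alike over all rows, and limma called 2 genes in their direct contrast. Chance values of controls shared by replicate number alone would leave r near 0 between replicates of different number, and it was 0.43. A control RNA common to all replicates would also give a positive r there, so this explanation stays open. An exchange of siRNAs between the groups is argued against, because in their direct contrast CCNG2 was lower in CCNG2 knockdown (-1.1 ± 0.14 SE) and XBP1 lower in XBP1 knockdown (0.865 ± 0.24 SE), with a higher p of 0.00118 in limma adjusted over these 2 genes; over all rows XBP1 did not pass (adjusted p = 0.894). Some CCNG2 siRNA mixed into the XBP1 group stays open, since CCNG2 stood at -0.195 ± 0.109 SE there, between the bounds set for the test. A biological relation between these genes stays open as untested.

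ESR1 was lowered less in the ESR1 and CCNG2 double than in the single knockdown, and CCNG2 was not lowered there. A double that lacks an effect of the CCNG2 siRNA should carry almost no weight of the CCNG2 profile when each replicate is regressed on both single profiles. The lower of both weights was 0.0554 and the other 0.0935, against 0.223 and 0.219 for the ESR1 profile. This lies between the bounds set for the test, so a missing siRNA effect and a weak one cannot be told apart.

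Sign changes of whole replicates or groups were used to ask whether chance could give as many genes. For CCNG2 knockdown (2348 genes, highest other 1), STC2 knockdown (1821, highest other 30) and tamoxifen (114, highest other 13) the 4 possible splits are too few for a share under 0.05. For the mean of all knockdowns (1666 genes, highest other 2080) 3 of 100 splits gave as many, which excludes chance only if the groups are independent. Several profiles correlate, such as CCNG2 with XBP1 knockdown (r = 0.651), and splits that call up to 2080 genes point to such a structure of the groups, so this share is weak evidence.

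The array of ESR1 knockdown whose channel carries a second label gave -1.21 for the ESR1 clone that fell most, and its dye partner -0.78. Over all rows, its turned values had an r of -0.143 with the mean of replicate 1, and those of its partner 0.472. Group means correlated with the mean dye profile most in AKT1 (r = -0.477) and STC2 knockdown (r = 0.445).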
